A study of Mus musculus with 24 samples.

How the data were processed

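Aortas of Ldlr knockout mice that carried a tamoxifen-inducible Cre under the Myh11 promoter and a ZsGreen1 reporter were studied at 0, 8, 16 and 26 weeks of Western diet. Per the labels' protocols, the tissue was digested with Liberase, hyaluronidase and DNase, stained with a cocktail of DNA-barcoded antibodies (CITE-seq) and with cell multiplexing tags, and sorted as nucleated, viable cells with or without ZsGreen1. The 24 deposited samples are the RNA, antibody and multiplexing libraries of 8 captures, 1 per lineage and week. Gene expression was read with the 10x Genomics 3' chemistry, in which each transcript carries a unique molecular identifier (UMI). The deposited matrices hold whole-number counts of UMIs per gene, per antibody and per multiplexing tag in each cell, not normalized, and are already filtered to cells and divided into the 3 multiplexed samples of each capture, as the files themselves show. They were made with Cell Ranger 6.1.2, per the file headers and the submitters' processing notes, on the mouse build mm10, per the submitters' processing notes; the settings for calling cells and assigning tags are not given in the sources used here. The matrices list 32286 genes including ZsGreen1, 128 antibodies, of which 9 are isotype controls, and 12 multiplexing tags, in 67545 cells. No coordinates were used, and genes carry the symbols paired with their identifiers in the files.

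Cells with at least 300 detected genes and at most 20% mitochondrial counts were kept, and doublets were called per matrix with scrublet as implemented in scanpy 1.11.5. The caller marked 403 cells, 0.251% in the SMC lineage and 1.14% in the non-SMC lineage. The first share is too low for a working caller, so doublets in the SMC lineage are in effect not removed. In all, 61175 cells stayed, 33393 of the SMC lineage and 27782 of the non-SMC lineage. The limit on mitochondrial counts removed 28.2%, 34.5% and 12.8% of the cells of the SMC-lineage matrices at 8 weeks, 19.6%, 26.5% and 23.1% at 16 weeks, and 11.9% in replicate 1 of the non-SMC lineage at 8 weeks; elsewhere it removed 0.328% to 5.07%. RNA counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen without mitochondrial, ribosomal, sex-linked and reporter genes, and scaled values were capped at 10. Cells of all matrices were clustered together, without batch integration and without the antibodies, on 30 principal components and 15 neighbours by the Leiden method (igraph 0.11.9) at resolution 1. A cluster took a class name, such as contractile SMC-like, from the markers listed in advance that it expressed, read together with its 10 leading genes detected in at least 25% of its cells (pseudocount 0.05 in the fold). Cluster 0 is in the contractile SMC-like class on its detected markers alone, since stress genes such as Hbegf, Atf3, Fos and Egr1 lead it; cluster 4 of that class and cluster 11 of the fibroblast-like class likewise have no listed marker of their class among these 10. Clusters led by other genes, resting on fewer than 3 markers or with few UMIs kept their numbers. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and scikit-learn 1.9.0 was used.

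Cells were not treated as replicates. Counts were summed over the kept cells of each matrix, or over the cells of a class where a matrix held at least 20 of them, and the sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, two-sided) with Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05, and between lineages also at a log2 fold change of at least 1 in size. The lineages were compared with 1 mean per lineage and week, each lineage over time with 1 mean per week, and modulated with contractile SMC-like cells with the matrix as a block. Antibody counts were tested in the same way with TMM over the panel. The resulting CPM of antibodies need not sum to the usual total, and folds of antibodies are relative to the panel. Gene sets were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes (prior count 2) over 23 lists. With an estimated correlation, 2 calls of the lists described held, both in fibroblast-like cells. Shares of classes were tested over all 369600 assignments of 12 matrices to 4 weeks by an exact permutation test of the arcsine square root of the share, adjusted over the classes of a lineage. The separation of the gates by an antibody is the area under the receiver operating characteristic curve of its counts per 10000 antibody counts of a cell, for cells of 1 matrix against 1 of the other lineage at the same week, averaged over the pairs.

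These tests, the lists, the class markers and the rule for named genes were set before the data were examined. The rule takes, for each RNA comparison, the 6 genes with the largest fold in each direction among those called, with a mean of at least 20 CPM and every replicate of 1 group on the same side of the other, without predicted, mitochondrial, ribosomal and sex-linked genes. It adds up to 4 members with the smallest p of each list described, and always Cd200, Cd200r1, Myh11 and Acta2. For antibodies it takes CD200 and the 6 largest folds in each direction. A fold against 0 counts was computed against 3 counts over the group, and with 1 to 3 counts a ratio with its 95% counting interval is given; intervals and floors cover counting error only.

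The antibody libraries were shallow, with 532093 to 2316498 counts per matrix against 7131074 to 27905029 gene counts. On simulated counts with the means and library sizes of these samples, changes of 2-fold were recovered for 94.1% of 68 genes between lineages, 81.9% of 72 over time in the SMC lineage, 75.0% of 60 in contractile SMC-like, 72.4% of 76 in fibroblast-like, 50% of 66 in endothelial-like and 35.7% of 70 in macrophage-like cells. Recovery was thus lowest in the macrophage-like and endothelial-like classes. It was counted at an adjusted p below 0.05 alone. Between lineages the median estimated log2 fold change of these 2-fold changes was 0.984. The limit of 1 used for lineage calls would thus leave out many of them. In the RNA comparisons, false calls made up 2.53% (macrophage-like) to 8.33% (fibroblast-like) of the simulated calls. These RNA simulations changed few genes, with directions drawn at random, whereas 5278 of 15136 genes were called between lineages, 1630 higher and 3648 lower. They thus do not test the scaling where many genes change, mostly in 1 direction. The biological coefficient of variation was 0.150 between lineages, 0.0809 over time in the SMC lineage and 0.302 for the antibodies between lineages. Replicates of every group differed from each other by more than counting error in all 24 pairs, so none is a copy of another; this does not show that they are independent animals.

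Alternatives tried were DESeq2 1.42.0, library totals in place of TMM, no filter on low genes, stricter cell filters (at least 500 genes and at most 10% mitochondrial counts), leaving out each replicate in turn, the number of the multiplexed sample as a block, isotype controls or the number of cells as the scale of antibody counts, Leiden resolutions of 0.5 and 2, and doublets kept. Chosen after the data were seen were 26 against 8 weeks, the omission of cluster 0 from the contractile SMC-like class, the addition of cluster 17 to the macrophage-like class, in its RNA and in the shares, and the omission of cells with over 5000 antibody counts. T cell-like cells were too few at 0 weeks, with 4 to 12 per matrix, for the comparison over time that had been planned, and it was not run. Multiplexing tag counts were used only to name the leading tag of each matrix, and as far as the deposited division of the cells rests on them.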

Results

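The series profiled aortic cells of Ldlr knockout mice, a model in which a cholesterol-rich Western diet produces atherosclerosis, after tamoxifen-inducible labelling of smooth muscle cells (SMC). A Cre recombinase driven by Myh11, the smooth muscle myosin heavy chain gene, switched on the green fluorescent reporter ZsGreen1, so that smooth muscle cells and the cells derived from them kept the label. ZsGreen1-positive cells (the SMC lineage) and ZsGreen1-negative cells (the non-SMC lineage) were sorted after 0, 8, 16 and 26 weeks of diet, and each of these 8 groups was captured separately. Every capture pooled 3 samples carrying cell multiplexing tags, which gave 24 matrices and 3 per group. Messenger RNA of 32286 genes, among them ZsGreen1, and the binding of 128 DNA-barcoded antibodies, 9 of them isotype controls, were counted in the same cells. The labels do not say that the 3 multiplexed samples of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical. Each week and each gate was also its own capture, so week, gate and capture cannot be separated.

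The matrices held 67545 cells, 38829 in the SMC lineage and 28716 in the non-SMC lineage, with 1436 to 4376 cells per matrix. Gene counts per matrix ranged from 14477603 to 27905029 in the SMC lineage and from 7131074 to 24248680 in the non-SMC lineage. The median number of RNA molecules (UMIs) per cell lay between 4165.5 and 9162 across matrices. Antibody counts were shallower, and the median per cell was 120 to 214 in the matrices at 0 weeks, 340 to 438 at 8 weeks, 368 to 539 at 16 weeks and 258 to 599.5 at 26 weeks. Filtering kept 61175 cells. The limit on mitochondrial counts removed 12.8% to 34.5% of the cells of the SMC-lineage matrices at 8 and 16 weeks, against 2.50% to 5.07% at 0 and 26 weeks.

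The lineages were compared to ask which genes distinguish labelled smooth muscle cells and their progeny from the other cells of the aorta. ZsGreen1 itself, the reporter used for the sort, was 107-fold higher in the SMC lineage (3412 ± 1127 against 30.7 ± 6.52 CPM, counts scaled to a common library size, SD, n = 12 each; log2 fold change 6.74, SE 0.11, adjusted p = 2.87e-19). The contractile genes Cnn1 (calponin), Myh11 and Acta2 (smooth muscle actin) were 12.2-fold, 11.3-fold and 9.78-fold higher, and Ibsp, a bone matrix sialoprotein, was 25.2-fold higher with a wide spread (163 ± 210 against 2.56 ± 4.48 CPM). Il17b, Sh3bgr and Fbxl22 completed the 6 largest increases, with log2 fold changes of 3.63, 3.59 and 3.59. The largest decreases were leukocyte and stromal transcripts. Igkc, an immunoglobulin light chain, had 0 counts in the SMC lineage and was at least 13035-fold lower, taking 3 counts over the 12 matrices as the floor. Retnla, expressed by alternatively activated macrophages, had 2 counts, a ratio of 50910 with a 95% counting interval of 14093 to 420387. The log2 fold changes of Lyz1, Ccr2, Ccl11 and Ccl21a were -11.90, -11.14, -10.37 and -10.27. Cd200r1, the receptor for CD200 on myeloid cells, was also lower (log2 fold change -7.32).

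Of the 21 measured contractile genes, 21 passed the test as higher in the SMC lineage, among them Sorbs1, Cald1, Flna and Smtn with log2 fold changes of 2.14, 2.52, 2.26 and 2.83 (camera adjusted p = 3.39e-06, and adjusted p = 0.304 with an estimated correlation). Of 12 genes of the TGF-beta response, 6 were higher, including Ltbp1, Tgfb2 and Ccn2 (1.59, 1.84 and 1.23), Tgfbi was lower at -7.39 and 5 did not pass (adjusted p = 0.00785, and adjusted p = 0.27 with an estimated correlation). Among 22 genes of modulated SMC and matrix, 2 were higher, 10 lower, with Ly6a, Dcn, Lgals3 and Klf4 at -5.62, -4.06, -2.17 and -1.39, and 10 did not pass (adjusted p = 0.443). All 12 measured complement genes were lower, as Serping1, C2, C1s1 and C1ra show (-3.63, -6.09, -3.28 and -2.89; adjusted p = 1.88e-05, and adjusted p = 0.265 with an estimated correlation). All 9 genes of antigen presentation by MHC class II were lower, with H2-DMa, H2-DMb1, H2-Eb1 and H2-Aa at -6.24, -3.94, -8.15 and -8.25 (adjusted p = 1.02e-04, and adjusted p = 0.265 with an estimated correlation).

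Markers of the cells that the gate should hold back moved with these groups. All 13 leukocyte markers were lower (Ptprc, Coro1a, Laptm5 and Cd52 at -8.00, -7.56, -7.44 and -8.00; adjusted p = 7.91e-05, and adjusted p = 0.27 with an estimated correlation). Of 10 endothelial markers, 9 were lower and 1 did not pass, with Vwf, Ecscr, Pecam1 and Cdh5 at -6.52, -4.31, -2.79 and -8.00 (adjusted p = 0.00104, and adjusted p = 0.27 with an estimated correlation). All 12 fibroblast markers were lower (Dpep1, Gsn, Cd34 and Scara5 at -8.67, -2.88, -5.05 and -6.67; adjusted p = 1.08e-05, and adjusted p = 0.265 with an estimated correlation). Of 9 mitochondrial transcripts, which rise in damaged cells and in cells rich in mitochondria, 6 were higher (mt-Co3 1.25, mt-Atp6 1.29, mt-Nd2 1.42) and 3 did not pass, mt-Co1 among them at 0.70 (adjusted p = 1.48e-05, and adjusted p = 0.265 with an estimated correlation). The counts adjusted over the list alone were equal for each of these 9 lists. In all, 5278 of 15136 genes were called between the lineages, 1630 higher and 3648 lower, at an adjusted p below 0.05 and a log2 fold change of at least 1 in size. Within single weeks the calls were 5469 at 0 weeks, 5112 at 8 weeks, 5246 at 16 weeks and 5360 at 26 weeks.

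The surface protein comparison addressed the purpose of the series, a surface marker of smooth muscle cells and their progeny. The CD200 antibody, against an immunoglobulin-family glycoprotein that signals to myeloid cells, showed the largest increase of the panel in the SMC lineage at 27.4-fold (log2 fold change 4.77, SE 0.19, adjusted p = 1.49e-14). The integrin subunits CD29 (beta 1), CD61 (beta 3) and CD51 (alpha V) followed with log2 fold changes of 4.63, 4.18 and 3.41, then CD27 and CD155 with 3.32 and 2.85. The leukocyte proteins CD11b, CD45 and CD48, MHC class II (I-A-I-E), CD38 and PIR-A-B were the lowest, at -5.30, -5.24, -4.89, -5.18, -4.60 and -4.49. CD200 was higher at each week, by 4.90, 4.62, 4.56 and 5.02 at 0, 8, 16 and 26 weeks, and the difference between the lineage effects at 26 and 0 weeks was 0.11 (adjusted p = 0.850). Cd200 RNA differed less between the lineages and was 1.69-fold higher in the SMC lineage, averaged over the 4 time points (520.8 ± 156 against 294 ± 46.3 CPM, n = 12 each, adjusted p = 2.21e-09). The RNA was not called at 0 weeks (log2 fold change 0.09, adjusted p = 0.569) and was higher by 0.98, 0.82 and 1.14 at 8, 16 and 26 weeks; the lineage effect at 26 weeks exceeded that at 0 weeks by 1.05 (adjusted p = 2.06e-04). Scaled by library totals alone, the value at 0 weeks was -0.04. The study chose CD200 on these cells, so its rank here is not independent evidence.

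Of 128 antibodies, 68 were called between the lineages on the average of the 4 time points, 29 higher and 39 lower. The balance depended on the scaling. Scaling by library totals gave 7 higher and 66 lower, by the isotype controls 13 and 50, and by the number of cells 6 and 86. The median log2 fold change of all antibodies was 0.22 here and -1.04, -0.39 and -1.56 under those scalings. At 0 weeks 66 were called (30 higher, 36 lower), with 16 and 40 by DESeq2, 13 and 40 by isotype controls, 7 and 60 by totals and 6 and 75 by cells. At 8 weeks 78 were called (37 and 41), with 13 and 57 by isotype controls, 8 and 68 by totals and 6 and 88 by cells. At 16 weeks 71 were called (28 and 43), with 13 and 50 by isotype controls, 8 and 63 by totals and 8 and 71 by cells. At 26 weeks 59 were called (26 and 33), with 18 and 37 by DESeq2, 14 and 48 by isotype controls, 11 and 56 by totals and 5 and 99 by cells.

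Cell by cell, CD200 separated the gates with the highest area under the receiver operating characteristic curve of the 128 antibodies, 0.960 ± 0.013 (SD over 4 weeks; 0.944 to 0.973). CD29 followed at 0.957 ± 0.023, a difference smaller than the spread between weeks, then CD61 at 0.930, CD51 at 0.830, CD9 at 0.657 and CD155 at 0.645. At the other end stood CD270 at 0.172, Ly-6A-E at 0.113 ± 0.155 and Ly-6C at 0.107, all 3 higher on non-SMC cells. Ly-6A-E, the stem cell antigen Sca1, ranged from 0.00588 to 0.335 between weeks. CD200 also ranked first on raw counts (0.959) and relative to the isotype controls (0.957). These areas describe the cells and carry no p-value.

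**Figure D1:**
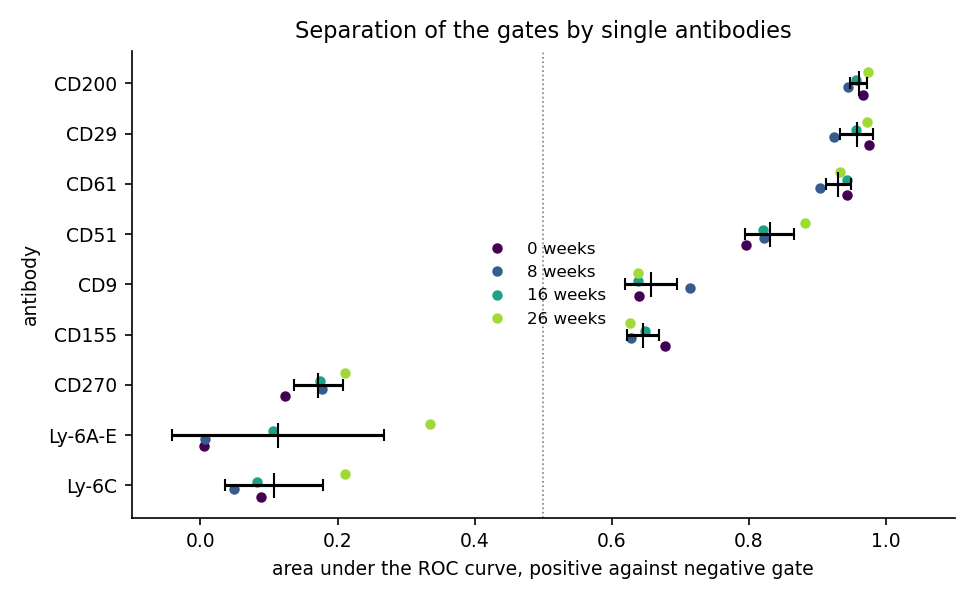
Area under the receiver operating characteristic curve (x axis, no unit) of the 6 antibodies with the highest and the 3 with the lowest mean area (y axis), positive against negative gate. Points are the 4 weeks, bars the mean and SD over weeks, and the dotted line marks 0.5, no separation; CD200 and CD29 lie at 0.960 and 0.957.

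Clusters were named from RNA markers alone, so the antibodies took no part in making the classes. An antibody is not independent of a class where its gene helped to define it. Vcam1, which encodes CD106, leads the modulated SMC-like cluster. Contractile SMC-like cells of the SMC lineage carried 4413 ± 459 CD200 counts per 10000 antibody counts (SD, n = 12 matrices), modulated SMC-like cells 2493 ± 402 (n = 8) and chondrogenic SMC-like cells 1751 ± 377 (n = 4). In the negative gate, contractile SMC-like cells carried 3492 ± 581 (n = 10) and modulated SMC-like cells 1219 ± 537 (n = 5). Fibroblast-like cells of the non-SMC lineage carried 452 ± 115, endothelial-like cells 344 ± 124 and macrophage-like cells 48.4 ± 19.1 (n = 12 each). The area for CD200 was 0.986 between contractile SMC-like and fibroblast-like cells, 0.999 against endothelial-like and 1.00 against macrophage-like cells. It was 0.925, 0.954 and 0.998 for modulated SMC-like cells against the same 3 classes, and 0.868 for chondrogenic SMC-like against fibroblast-like cells. Counted per cell, CD200 averaged 218 on modulated and 150 on contractile SMC-like cells, and 14.2, 48.6 and 4.80 on fibroblast-like, endothelial-like and macrophage-like cells. Cd200 RNA averaged 790 ± 99.8 CPM in modulated and 814 ± 200 in chondrogenic SMC-like cells, 653 ± 235 in endothelial-like, 449 ± 110 in contractile SMC-like, 369 ± 73.0 in fibroblast-like and 13.97 ± 9.85 in macrophage-like cells. These means cover different weeks, since modulated and chondrogenic cells had no matrix at 0 weeks, and give no ranking. Within weeks, endothelial-like and contractile SMC-like cells stood at 308 and 271 CPM at 0 weeks, 643 and 506 at 8, 828 and 496 at 16, and 834 and 524 at 26 weeks. Modulated cells were at 899, 680 and 827 CPM at 8, 16 and 26 weeks, and fibroblast-like cells at 353 CPM at 0 weeks.

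**Figure D2:**
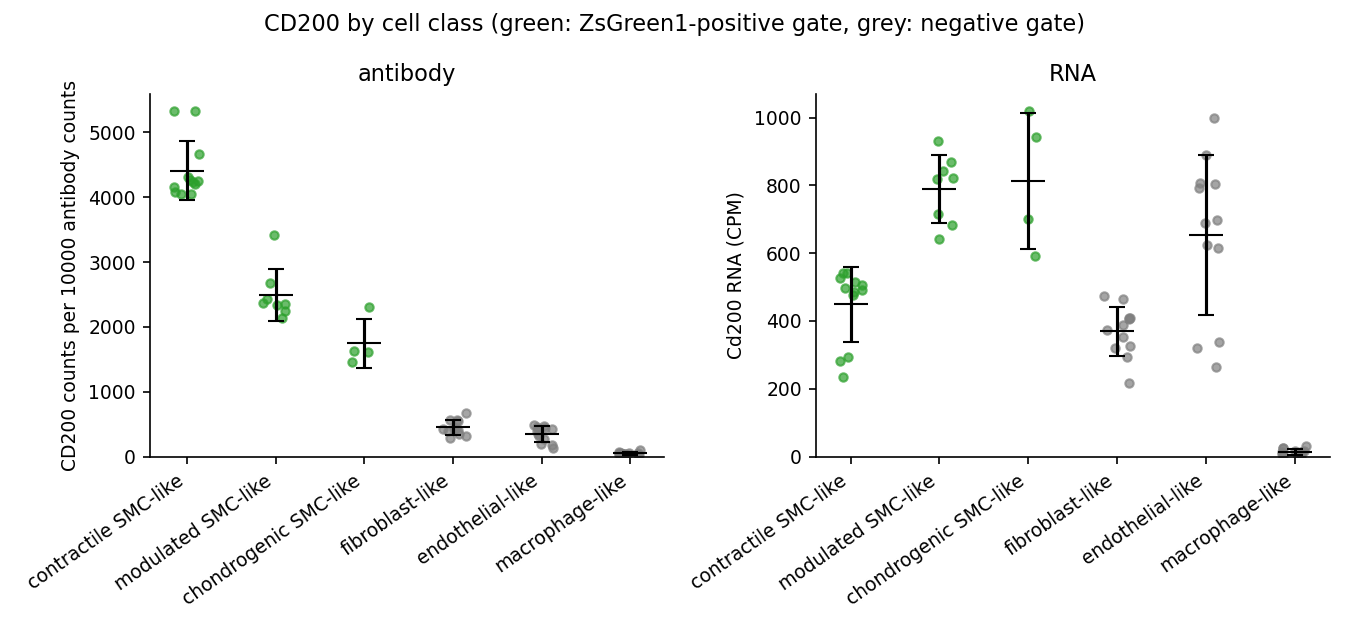
CD200 antibody counts per 10000 antibody counts (left y axis) and Cd200 RNA in CPM (right y axis) by cell class (x axis). Each point is a matrix with at least 20 cells of the class, green for the positive and grey for the negative gate, and bars give the mean and SD; SMC-like classes are those of the positive gate, in which every contractile SMC-like matrix lies above 4044 antibody counts, and every fibroblast-like matrix of the negative gate lies below 675.

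The makeup of each gate was followed over the diet. In the SMC lineage the contractile SMC-like share went from 93.1% ± 0.856 of kept cells at 0 weeks to 79.8% ± 2.07, 66.0% ± 7.82 and 56.4% ± 1.42 at 8, 16 and 26 weeks (SD, n = 3; exact permutation test, two-sided, adjusted p = 3.57e-04). The modulated SMC-like cluster, led by Vcam1, Lcn2, Spp1 and Tnfrsf11b, took 0.0379%, 0.961%, 13.1% and 30.4% (SD 0.0425, 0.240, 5.23 and 1.00; adjusted p = 3.57e-04). For both classes the unadjusted p of 6.49e-05 was the smallest that the 369600 assignments allow. Chondrogenic SMC-like cells, led by Ibsp, Col2a1 and Chad, were at 0% at 0 and 8 weeks, 0.989% ± 0.674 at 16 and 1.59% ± 0.152 at 26 weeks (adjusted p = 0.00357). Cluster 1, led by Rgs5, Lamc3 and Itih4 and left unnamed, went from 4.82% ± 1.08 through 16.3% ± 1.73 and 15.8% ± 2.66 to 8.02% ± 1.12 (adjusted p = 0.00238), and the unnamed cluster 5, led by Hapln1 and Acan, was at 1.36%, 2.06%, 2.41% and 1.55% (adjusted p = 0.0204). Between 0 and 26 weeks, cycling mesenchymal cells went from 0.0922% to 0.762% (adjusted p = 0.00548), cluster 12 from 0% to 0.223% (0.00548), macrophage-like cells from 0.0214% to 0.538% (0.0127) and fibroblast-like cells from 0.181% to 0.0523% (0.0191). The macrophage-like result did not pass without the SMC replicate 2 at 26 weeks (adjusted p = 0.0534). In replicates 2 and 3 at 26 weeks the macrophage-like cells held 529 and 1244 CPM of ZsGreen1. Contractile SMC-like cells with clusters 1 and 5 held 3558 to 3967 CPM in that week. Doublets in this lineage were in effect kept, so an origin of these cells in smooth muscle is not shown. The fibroblast-like result did not pass without replicate 3 at 0 weeks (0.0696) or replicate 1 at 26 weeks (0.0554), nor at a clustering resolution of 0.5 (0.136) or 2 (0.457). Clusters 8 and 13 did not pass (adjusted p = 0.103 and 0.124), so 9 of 11 classes passed. Cluster 8 passed without replicate 1 at 0 weeks (0.0139). The loss of cells to the mitochondrial limit at 8 and 16 weeks and the gate on ZsGreen1 can both set these shares.

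In the non-SMC lineage the fibroblast-like share fell from 55.5% ± 2.98 to 38.6% ± 10.7, 21.9% ± 2.92 and 16.8% ± 3.16 (adjusted p = 0.0013; 0.0657 at a clustering resolution of 0.5), while the macrophage-like share rose from 2.90% ± 1.48 to 11.9% ± 3.81, 26.0% ± 2.94 and 28.8% ± 4.90 (adjusted p = 0.00216). Together with cluster 17, described below, that share was 15.6% ± 5.30, 12.1% ± 4.01, 26.1% ± 3.01 and 28.8% ± 4.89 (adjusted p = 0.016), so the size of the rise and its presence at 8 weeks depend on the naming of that cluster. The unnamed cluster 12, led by Saa3, Chl1, Cfb, Mmp3 and C3, was kept out of the fibroblast-like class and went from 0.305% to 0.927%, 8.90% and 17.1% (adjusted p = 0.0013). Counted as fibroblast-like, it would make the fall of that class smaller, so the size of the fall depends on its naming. The 2 together were not tested, and the RNA comparison of fibroblast-like cells left cluster 12 out as well. Cluster 17, led by the inflammatory genes Cxcl2, Tnf, Hmox1, Ccl4 and Cxcl10 with Lyve1 among its 10 leading genes, and kept out of the macrophage-like class, held 12.7% ± 3.93 at 0 weeks and 0.199%, 0.0666% and 0% later (adjusted p = 0.00928). T cell-like cells were at 0.277%, 4.65%, 3.16% and 0.640% (adjusted p = 0.00519) and dendritic cell-like cells at 0.827%, 4.07%, 4.13% and 3.87% (adjusted p = 0.0341). Endothelial-like cells were at 5.32%, 3.82%, 7.72% and 8.26% (adjusted p = 0.0146), a result that did not pass without replicate 1 (0.0524) or replicate 3 (0.0531) at 8 weeks. Between 0 and 26 weeks, modulated SMC-like cells, here sorted as ZsGreen1-negative, went from 0.0575% to 2.24% (adjusted p = 0.00545, and 0.147 at a resolution of 0.5) and cycling leukocytes from 0.741% to 3.19% (adjusted p = 0.00887). These p-values, too, test any difference among the 4 weeks and not 26 against 0 weeks alone.

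Among the 20 classes of the non-SMC lineage, 9 passed. The remaining 11 gave adjusted p of 0.0573 for cycling mesenchymal cells (0.0199 without replicate 1 at 26 weeks, 0.0372 without replicate 2 at 8 weeks and 0.0447 with the stricter filter on cells), 0.0955 for monocyte-like, B cell-like and chondrogenic SMC-like cells (the first 0.0356 at a resolution of 2, the last 0.0364 without replicate 2 at 16 weeks), 0.192 for cluster 1 (0.0113 without replicate 2 at 8 weeks), 0.430 for neutrophil-like, 0.503 for cluster 8 (0.0253 at a resolution of 2), 0.541 for contractile SMC-like, 0.553 for mesothelial-like cells and cluster 5, and 0.797 for cluster 13. Cluster 8, with few RNA molecules per cell, held between 11.8% and 15.2% in each week. Contractile SMC-like cells held 4.65% ± 2.72, 10.97% ± 10.94, 5.57% ± 4.60 and 1.57% ± 1.12 of this gate. Monocyte-like cells went from 0.264% to 2.30% between 0 and 26 weeks and neutrophil-like cells from 0.226% to 1.44%. Only ZsGreen1 fluorescence and viability dyes defined the gates, so all shares are shares of what the digestion and the sort let through.

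**Figure D3:**
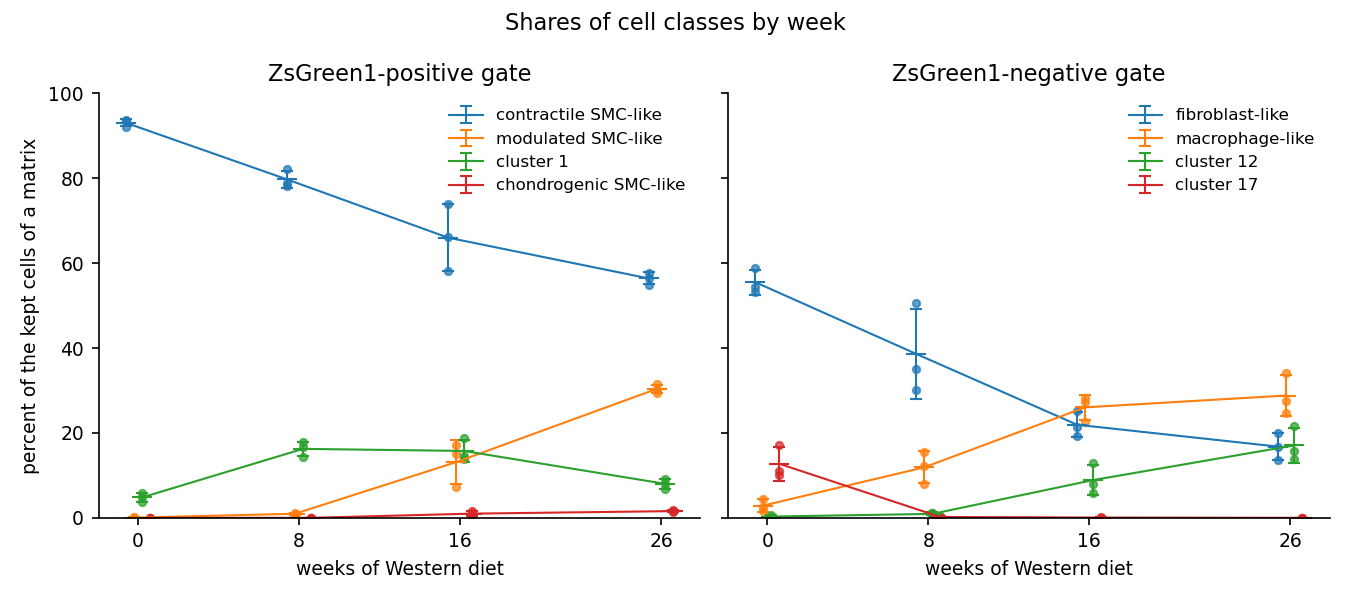
Percent of the kept cells of a matrix (y axis) against weeks of Western diet (x axis) for 4 classes in the positive gate (left) and 4 in the negative gate (right). Points are matrices, 3 per week, and bars the mean and SD. The contractile SMC-like share goes from 93.1% to 56.4%. The fibroblast-like share, without cluster 12, goes from 55.5% to 16.8%, and cluster 12 of the negative gate from 0.305% to 17.1%.

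Over all SMC-lineage cells, between 0 and 26 weeks, Spp1 (osteopontin) rose from 0.522 ± 0.183 to 5767 ± 327 CPM (n = 3 each; log2 fold change 13.41, SE 0.94, adjusted p = 5.18e-08). Serpina3n and Prg4 (lubricin) rose by 10.44 and 10.25 on the log2 scale. Lcn2 (lipocalin 2) had 1 count at 0 weeks and reached 1273 ± 85.0 CPM, a ratio of 71028 with a counting interval of 12748 to 2.81e+06. The acute-phase gene Hp and the cartilage collagen Col2a1 had 0 counts at 0 weeks and were at least 4948-fold and at least 2871-fold higher. Myh11 fell from 3159 ± 118 to 1324 ± 67.7 CPM (log2 fold change -1.25, SE 0.08, adjusted p = 2.27e-08) and Acta2 by 0.69, whereas Cd200 rose from 272 ± 27.5 to 674 ± 5.14 CPM (1.31, SE 0.07, adjusted p = 3.29e-09). The largest falls were in the immediate-early and growth regulators Egr1 (-2.49), Atf3 (-2.36), Fos (-2.22), Id1 (-2.13) and Sertad1 (-2.11) and the histone gene Hist1h1e (-2.32).

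Of 21 contractile genes, 17 fell, with Lmod1, Tpm2 and Tpm1 at -1.33, -1.08 and -0.95, and 4 did not pass (adjusted p = 1.88e-05, and adjusted p = 0.469 with an estimated correlation). Of 22 genes of modulated SMC and matrix, 18 rose, 3 fell and 1 did not pass, with Lum, Vcam1, Thbs1 and Tnfrsf11b at 8.85, 6.1, 5.38 and 4.59 (adjusted p = 1.13e-05, and adjusted p = 0.465 with an estimated correlation). The chondrogenic and osteogenic list rose in 17 of 18 genes, including Chad (9.04), the bone transcription factor Runx2 (3.86), Comp (3.64) and Chst11 (2.73), and 1 did not pass (adjusted p = 1.13e-05, and adjusted p = 0.465 with an estimated correlation). All 12 complement genes rose, with C3, C4b, C1s1 and C1ra at 8.55, 7.49, 3.54 and 3.47 (adjusted p = 3.65e-05, and adjusted p = 0.465 with an estimated correlation). Of 17 chemokines and NF-kB targets, 15 rose, among them Ccl2 (8.66), Icam1 (4.25) and Cxcl12 (2.89), Nfkbia fell by 1.66 and 1 did not pass (adjusted p = 8.48e-05, and adjusted p = 0.443 with an estimated correlation). The lipid-associated macrophage list, which holds genes of lipid efflux and lysosomes that other cells also use, rose in 17 of 19 genes, with Gpnmb, Abcg1 and Abca1 at 4.97, 4.14 and 2.63 (adjusted p = 1.13e-05, and adjusted p = 0.443 with an estimated correlation). All 18 cholesterol synthesis genes fell, Dhcr24, Sqle, Fdps and Mvk by 2.10, 2.07, 1.90 and 1.11 (adjusted p = 1.13e-05, and adjusted p = 0.465 with an estimated correlation).

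Beside these groups, 14 of 18 dissociation stress genes, which tissue digestion induces, fell between 0 and 26 weeks, with Ier2 and Jun at -1.72 and -1.94, 1 rose and 3 did not pass; 16 fell adjusted over the list alone (adjusted p = 1.13e-05, and adjusted p = 0.443 with an estimated correlation). Leukocyte markers rose in 11 of 11 measured genes from low levels, C1qc from 0.750 to 27.3 CPM and Fcer1g from 1.06 to 25.6 CPM, with Cd52 and Tyrobp at 5.31 and 4.88 (adjusted p = 0.00738, and adjusted p = 0.567 with an estimated correlation). Doublets and leukocytes let through by the gate are not excluded as their source. Of 16 cell cycle genes, 10 rose and 6 did not pass, with Birc5, Ccnb1, Cdk1 and Top2a at 3.17, 3.10, 2.86 and 1.87 (adjusted p = 0.0459, and adjusted p = 0.584 with an estimated correlation). Except for the stress genes, the counts adjusted over the list alone were equal. Against 0 weeks, 4930 of 13397 genes were called at 8 weeks (2578 higher, 2352 lower), 6373 at 16 weeks (3413 and 2960) and 8381 at 26 weeks (4296 and 4085). These sums mix changes within cells with the changes in class shares.

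**Figure D4:**
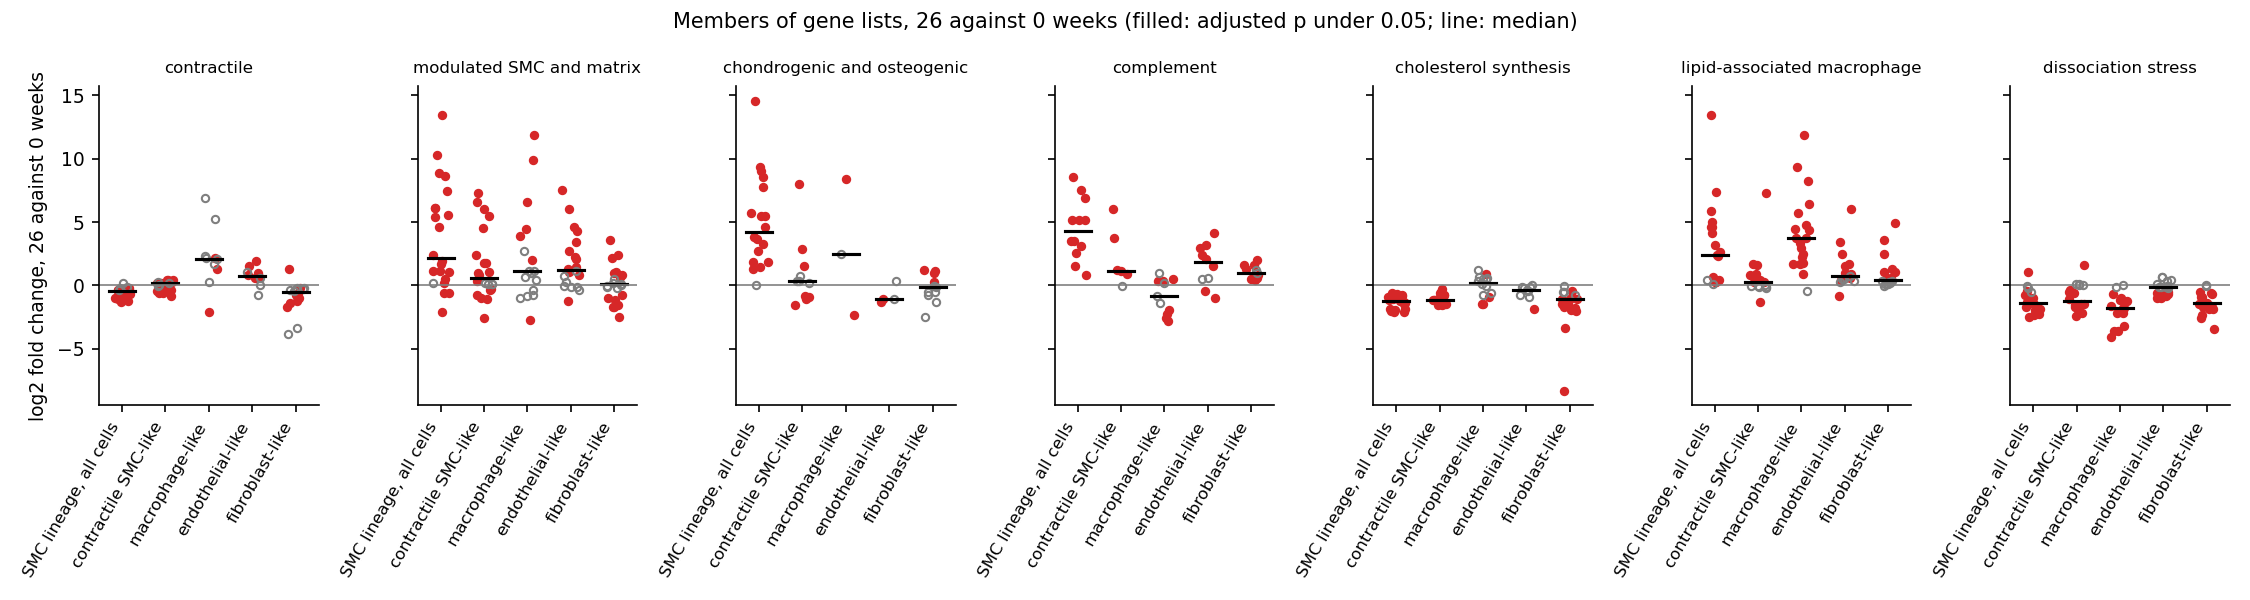
Log2 fold change at 26 against 0 weeks (y axis) of each measured gene of 7 fixed lists (panels) in all SMC-lineage cells and 4 cell classes (x axis). Points are genes, filled where the adjusted p was under 0.05, and lines are medians; in SMC-lineage cells 17 of 21 contractile genes fell and 12 of 12 complement genes rose.

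At the surface of SMC-lineage cells, Ly-6A-E, the integrin subunit CD49b, the adhesion molecules CD54 (ICAM1) and CD106 (VCAM1), and the leukocyte proteins CD45 and CD11b showed the largest increases at 26 against 0 weeks, with log2 fold changes of 4.94, 4.47, 3.97, 3.42, 3.80 and 3.70. CD11b was not called without the replicate 1 (adjusted p = 0.0629) or 3 (0.0547) at 0 weeks. Doublets, in effect kept in this lineage, are not excluded as a source of CD45 and CD11b. CD31, CD102, CD29, CD61, CD49a and CD49d decreased relative to the panel by -3.64, -2.25, -1.73, -1.59, -1.38 and -1.29, and CD200 by -1.07 (SE 0.13, adjusted p = 7.93e-05). Under the same scaling CD200 rose at 8 weeks (0.51, SE 0.13, adjusted p = 0.0207) and stood at -0.15 at 16 weeks (adjusted p = 0.396), each against 0 weeks. As for RNA, these sums mix changes on cells with the changes in class shares. Per 10000 antibody counts, contractile SMC-like cells carried 4058 CD200 counts at 0 weeks and 4273 at 26 weeks. Modulated SMC-like cells carried 2372 at 26 weeks. CD102 was not called without replicate 3 at 0 weeks (-0.67, adjusted p = 0.390), replicate 1 (0.0558), 2 (0.0576) or 3 (0.0554) at 8 weeks, replicate 2 at 16 weeks (0.0672) or replicate 2 (0.116) or 3 (0.124) at 26 weeks, nor under any other scaling but that of DESeq2. Scaled by the number of cells, CD200 went the other way (0.39, adjusted p = 0.00851), CD49a and CD49d stood at 0.08 and 0.18, and CD29 (adjusted p = 0.0521) and CD61 (0.356) did not pass. Of 128 antibodies, 27 were called at 8 weeks (18 higher, 9 lower), 41 at 16 weeks (25 and 16) and 67 at 26 weeks (29 and 38). Other scalings moved the balance to 19 and 17 by DESeq2, 13 and 20 by totals and 92 and 1 by cells at 8 weeks. At 16 weeks they gave 30 and 8 by isotype controls and 118 and 0 by cells, and at 26 weeks 64 and 7 by totals, 35 and 15 by isotype controls and 115 and 1 by cells. The count at 8 weeks was 15 without the SMC replicate 1 or replicate 3 at 0 weeks and 14 without replicate 2 at 8 weeks.

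Modulated and contractile SMC-like cells were compared within the same 8 matrices, so capture and staining did not differ. CD54, Ly-6A-E, CD49b, the ectonucleotidase CD73, the integrin subunit CD49f and I-A-I-E were higher on modulated cells, with log2 fold changes of 4.97 (SE 0.26, adjusted p = 4.18e-08), 4.43, 4.19, 3.90, 3.77 and 3.51. Doublets with leukocytes, in effect kept in this lineage, are not excluded as a source of I-A-I-E. CD279, CD27, CD29, IL-33Ralpha, TER-119 and IgD were lower at -1.19, -1.16, -1.03, -1.01, -1.01 and -0.93, and CD200 at -0.47 (SE 0.13, adjusted p = 0.011). Scaled by the isotype controls CD200 (adjusted p = 0.104), CD279 (0.0681), IL-33Ralpha (0.0541) and TER-119 (0.0596) did not pass, and per cell CD200 was higher on modulated cells (0.43, adjusted p = 5.86e-04), while none of the other 6 passed per cell. Of 128 antibodies, 67 were called, 37 higher and 30 lower. The split was 36 and 48 by DESeq2, 27 and 76 by library totals, 37 and 10 by isotype controls and 92 and 0 by cells. CD279 was not called without replicate 1 at 8 weeks (adjusted p = 0.0511) or replicate 2 (0.0565) or 3 (0.0844) at 26 weeks. IL-33Ralpha was not called without replicate 1 at 16 weeks (0.0657) or replicate 1 (0.0625), 2 (0.0523) or 3 (0.0515) at 26 weeks, nor without the matrix as a block (0.0742). TER-119 and IgD averaged 161 and 154 CPM over all SMC-lineage cells, little above the highest isotype control at 128.5 CPM.

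Against fibroblast-like cells of the non-SMC lineage, modulated SMC-like cells carried more CD106, CD200, CD61, CD49b, CD29 and the transferrin receptor CD71, with log2 fold changes of 3.81, 3.45, 3.22, 3.21, 3.08 and 2.89. CD200 was 10.9-fold higher (SE 0.17 on the log2 scale, adjusted p = 9.15e-12). Counts relative to the panel were higher in fibroblast-like cells for CD26 (dipeptidyl peptidase 4), at -5.89 in this comparison, CD90.2 (Thy1, -3.65), Ly-6C (-3.24), CD55 (-3.16), CD115 (-3.13) and CD2 (-2.87). Over the samples of this comparison CD2 averaged 17.33 CPM, below every isotype control (27.77 to 124 CPM). CD115 averaged 89.05 CPM, within the range of these controls. Binding above background is thus not shown for CD2 or CD115, and doublets with leukocytes were not tested as their source. CD2 was not called without the SMC replicate 1 (adjusted p = 0.0858) or 2 (0.0849) at 8 weeks, nor by DESeq2 (0.0569). Of 127 antibodies, 60 were called, 26 higher and 34 lower, with 17 and 85 by library totals and 30 and 17 by cells.

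Within contractile SMC-like cells, Acta2 was at 30041.5 ± 778 CPM at 0 weeks and 29290.5 ± 1797 at 26 weeks (n = 3 each; log2 fold change -0.04, adjusted p = 0.673), and it fell by 0.19 with cluster 0 of the class left out (adjusted p = 0.0143). Myh11 fell from 3183 ± 126 to 2141 ± 122 CPM (-0.57, SE 0.05, adjusted p = 1.20e-08) and Cd200 rose from 263 ± 28.8 to 532 ± 25.2 CPM (1.02, SE 0.07, adjusted p = 3.05e-10). Spp1 rose from 0.392 ± 0.170 to 60.8 ± 5.87 CPM (7.29), which is 1.06% of its level over all SMC-lineage cells at 26 weeks. Transcripts of modulated cells that contractile cells should lack stood at 0.653% (Prg4) to 1.92% (Serpina3n) of that level, and Spp1 lay within that range, which free RNA can give. The other 5 largest increases were AC149090.1 (2.87), Nmt1 (2.61), Ndufb1-ps (2.58), Atp5k (2.38) and Gstp1 (2.35). The largest falls were in Pcolce2 (-3.29), the transcription factor Klf4 (-2.60), the clock gene Dbp (-2.52), Egr1 (-2.39), Hist1h1e (-2.14) and the cytokine signalling inhibitor Socs3 (-2.13).

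Among 21 contractile genes, 10 rose, such as Smtn (0.41), 7 fell, such as Lmod1 (-0.80) and Tpm2 (-0.44), and 4 did not pass (adjusted p = 0.899). All 18 cholesterol synthesis genes fell, Fdps, Dhcr24, Hmgcs1 and Mvk by 1.48, 1.44, 1.18 and 0.93 (adjusted p = 9.65e-05, and adjusted p = 0.505 with an estimated correlation). Of 22 genes of modulated SMC and matrix, 12 rose, 6 fell and 4 did not pass, with 14 rising adjusted over the list alone. Lum went from 0.973 to 44.6 CPM (5.45) and Dcn rose by 1.76 (adjusted p = 0.0344, and adjusted p = 0.505 with an estimated correlation). At 26 weeks Lum and Dcn stood at 1.29% and 1.04% of their level over all SMC-lineage cells, within the range that free RNA can give. Of 6 complement genes, 5 rose, with C3, C4b, C1s1 and C1ra at 6.01, 3.71, 1.22 and 1.12 (adjusted p = 0.0155, and adjusted p = 0.505 with an estimated correlation). They stood at 2.04%, 4.298%, 18.3% and 17.7% of that level. Dissociation stress genes fell in 13 of 18 cases, with Fos and Ier2 at -1.94 and -1.60, 1 rose and 4 did not pass (adjusted p = 0.0011, and adjusted p = 0.505 with an estimated correlation). Save for the modulated list, the counts adjusted over the list alone were equal. Calls numbered 4871 of 12174 genes at 8 weeks (2508 higher, 2363 lower), 5035 at 16 weeks (2574 and 2461; 1989 and 3184 by library totals) and 6354 at 26 weeks (3139 and 3215), and 26 against 8 weeks gave 4172. Different clusters held most of the class over time: cluster 0, led by the stress genes Hbegf, Atf3, Fos and Egr1, held 63.0% at 0 weeks, cluster 2 59.2% and 53.6% at 8 and 16 weeks, and cluster 3 56.0% at 26 weeks.

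In macrophage-like cells, Spp1 rose from 7.71 ± 10.9 to 14487 ± 2157 CPM between 0 and 26 weeks (n = 3 each; log2 fold change 11.86, SE 0.69, adjusted p = 6.01e-09), and Trem2, a lipid-sensing receptor, from 152 ± 5.18 to 2066 ± 171 CPM (3.76). Npy, Abi3, F7, Thbs1 and Apoc1 had 0 counts at 0 weeks and were at least 102-fold, 25.9-fold, 20.7-fold, 17.5-fold and 15.5-fold higher, although Apoc1 was not called without replicate 2 at 0 weeks (adjusted p = 0.0702). Lyve1, a marker of resident arterial macrophages, fell from 1062 ± 113 to 43.0 ± 18.5 CPM (-4.57), together with Mmp9 (-5.88), Retnla (-4.90), the phosphatidylserine receptor Timd4 (-4.54), Cmah (-4.31) and the heat-shock gene Hspa1b (-4.08). Cd200 RNA had 1 count at 0 weeks and 25.5 ± 11.8 CPM at 26 weeks, a ratio of 35.3 with a counting interval of 6.30 to 1397. Cd200r1 was at 23.2 ± 16.0 and 27.5 ± 7.17 CPM (adjusted p = 0.155, or 2.59e-04 with cluster 17 added to the class, 0.0415 with no filter on low genes and 0.0370 without replicate 3 at 0 weeks). Acta2 was at 4.77 ± 5.92 and 36.9 ± 33.8 CPM (log2 fold change 2.17, adjusted p = 0.284; 0.0499 by DESeq2 and 1.12e-06 with no filter on low genes), and Myh11 had 0 counts at 0 weeks and 24 at 26 weeks (adjusted p = 0.486).

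Of 19 lipid-associated macrophage genes, 18 rose, including Fabp5 (8.24) and Lgals3 (4.42), and 1 did not pass. The latter fell adjusted over the list alone (adjusted p = 1.18e-09, and adjusted p = 0.411 with an estimated correlation). All 10 resident macrophage genes fell, with F13a1 and Folr2 at -3.52 and -2.64 (adjusted p = 1.53e-06, and adjusted p = 0.508 with an estimated correlation). Dissociation stress genes fell in 16 of 18 cases, Jun, Egr1 and Ier3 by 3.16, 3.57 and 2.13 (adjusted p = 1.18e-09, and adjusted p = 0.469 with an estimated correlation). Of 9718 genes, 1279 were called at 8 weeks (770 higher, 509 lower), 2224 at 16 weeks (1240 and 984) and 4256 at 26 weeks (2201 and 2055). Scaled by library totals, the splits were 511 and 683, 700 and 1522, and 1096 and 3591. The median log2 fold change of all genes at 26 weeks was then -0.54, against -0.02 with TMM. The class held 244 cells at 0 weeks. Without replicate 1 or 2 at 0 weeks or replicate 2 at 8 weeks the count at 8 weeks was 802, 662 or 794, and without replicate 2 at 0 weeks that at 16 weeks was 1396. Cluster 15 held 98.0% of the class at 0 weeks and cluster 16 59.6% at 26 weeks. With cluster 17 added to the class the calls were 3772, 4921 and 6644.

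In endothelial-like cells, Prnd and Glycam1, a ligand of L-selectin, had 0 counts at 0 weeks and were at least 70.3-fold and at least 46.6-fold higher at 26 weeks. Gal, Mmp3, Kit and Ankrd1 had 1 to 3 counts, with ratios of 328 (counting interval 58.7 to 12997), 282 (50.4 to 11159.6), 179 (31.9 to 7103) and 181 (49.98 to 1500.03). At 26 weeks Mmp3 stood at 6.45% of its level over all non-SMC-lineage cells, with a UMI in 9.25% of the endothelial-like cells, beside 3.503% for Spp1 and 2.23% for Saa3. Lum, Dcn and Vcan stood at 33.9%, 57.6% and 286%. In the 49 T cell-like cells of that week, which should not make them, Mmp3, Lum and Dcn stood at 19.7%, 30.3% and 35.6%, with a UMI in 12.2%, 10.2% and 10.2% of the cells, and Vcan had none. In macrophage-like cells the 4 stood at 0.693%, 0.700%, 0.883% and 1.96%. RNA from other cells is thus not excluded for Mmp3, Lum and Dcn in endothelial-like cells. Cd200 rose from 311 ± 41.0 to 897 ± 164 CPM (n = 3 each; log2 fold change 1.53, SE 0.14, adjusted p = 1.29e-06) and Acta2 from 370 ± 93.3 to 1388 ± 185 CPM (1.91). The falls were led by Lars2 (-3.34), Tppp3 (-3.26), the basement membrane collagen Col4a3 (-3.08), Dbp (-3.05), H2-DMa (-2.93) and the adrenergic receptor Adra2a (-2.88).

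Of 13 flow and identity genes, 10 fell, with Gja4, Nos3 (endothelial nitric oxide synthase) and Pecam1 at -1.30, -0.92 and -0.88, 1 rose and 2 did not pass (adjusted p = 6.34e-04, and adjusted p = 0.227 with an estimated correlation). Endothelial activation genes rose in 7 of 11 cases, with Lrg1, Plvap and P-selectin (Selp) at 3.27, 1.80 and 1.53, and 1 fell, Cd74 at -3.31. Adjusted over the list alone 2 fell (adjusted p = 0.0055, and adjusted p = 0.149 with an estimated correlation). Of 12 TGF-beta response genes, 9 rose, with Ltbp2, Col4a2 and Col4a1 at 5.13, 2.13 and 1.45, and Smad7, an inhibitor of the pathway, fell by 1.17 (adjusted p = 6.34e-04, and adjusted p = 0.104 with an estimated correlation). Of 6 MHC class II genes, 5 fell and 6 fell adjusted over the list alone, with H2-Aa and H2-DMb1 at -2.20 and -2.01 (adjusted p = 0.0055, and adjusted p = 0.4 with an estimated correlation). H2-DMb1 was not called without replicate 3 at 0 weeks (adjusted p = 0.0663), and H2-Aa not without replicate 2 (0.0609) or 3 (0.0521) at 0 weeks or replicate 3 at 26 weeks (0.0555). Of 20 genes of modulated SMC and matrix, 12 rose, with Vcan, Lum and Dcn at 4.59, 4.31 and 2.24, and 1 fell, Klf4 at -1.20, or 2 adjusted over the list alone (adjusted p = 0.00114, and adjusted p = 0.208 with an estimated correlation).

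Leukocyte markers moved with these groups in endothelial-like cells, where 7 of 8 rose, Fcer1g, C1qb and Laptm5 by 4.14, 3.20 and 2.26, and Cd74 fell (adjusted p = 0.0301, and adjusted p = 0.465 with an estimated correlation). Macrophage-like cells held a larger share of this gate at 26 weeks, so their free RNA and doublets are not excluded as the source of these rises. Dissociation stress genes fell in 8 of 18 cases, such as Hspa1a (-1.01) and Jun (-0.81), and 2 rose adjusted over the list alone (adjusted p = 0.0956). Of 9 mitochondrial transcripts, 5 fell, with mt-Nd2, mt-Nd5 and mt-Atp6 at -0.82, -0.55 and -0.45, and 4 did not pass (adjusted p = 0.0301, and adjusted p = 0.465 with an estimated correlation). The smaller class, 414 cells at 0 weeks and 562 at 26 weeks, gave 545 calls among 8030 genes at 8 weeks (327 higher, 218 lower), 713 at 16 weeks (395 and 318) and 2324 at 26 weeks (1242 and 1082; 1008 and 1336 by library totals). The count at 8 weeks was 304, 360 or 259 without replicate 1, 2 or 3 at 0 weeks and 270 without replicate 2 at 8 weeks. That at 16 weeks was 428 without replicate 1 at 0 weeks, 378 without replicate 3 at 16 weeks and 474 by DESeq2, and 26 against 8 weeks gave 1207.

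In fibroblast-like cells, Hp and Lcn2, which encode acute-phase proteins, rose from 22.4 ± 9.17 to 644 ± 329 and from 4.17 ± 3.69 to 217 ± 158 CPM (n = 3 each; log2 fold changes 4.83 and 5.55). Snhg9 (5.24), Dmkn (4.40), Hist4h4 (3.82) and Krtdap (3.55) made up the other largest increases. The orphan nuclear receptors Nr4a2 (-4.06) and Nr4a3 (-3.39), Atf3 (-3.45), Irs2 (-3.13), the NF-kB inhibitor gene Nfkbia (-3.06) and Tiparp (-2.90) fell most. Acta2 fell from 304 ± 150 to 129 ± 21.1 CPM (-1.25, adjusted p = 0.00236). Over all non-SMC-lineage cells Acta2 went from 2695 to 906 CPM and Myh11 from 304 to 44.5 CPM. Free RNA of smooth muscle cells is thus not excluded for these 2 genes in fibroblast-like cells. Myh11 was at 8.16 ± 9.82 CPM at 0 weeks and had 3 counts at 26 weeks, a ratio of 15.04 with a counting interval of 5.08 to 73.5. It did not pass (adjusted p = 0.0585), but passed by DESeq2 (0.0190), with no filter on low genes (8.38e-12) and without replicate 1 (0.0320) or 3 (0.00767) at 0 weeks. Cd200 was at 360 ± 41.2 and 443 ± 40.8 CPM, which did not pass (0.30, adjusted p = 0.0843), but passed without replicate 3 at 0 weeks (0.38, adjusted p = 0.0420) or replicate 3 at 8 weeks (adjusted p = 0.0344), and with no filter on low genes (0.0130).

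Of 11 complement genes, 9 rose, C3 from 1111 ± 304 to 3393 ± 545 CPM, with C4b, Cfb and Serping1 at 2.0, 1.29 and 0.60 (adjusted p = 3.44e-06, and adjusted p = 0.191 with an estimated correlation). Of 17 cholesterol synthesis genes, 13 fell and 14 fell adjusted over the list alone, with Sqle, Cyp51 and Srebf2, the transcription factor that controls the pathway, at -3.37, -2.03 and -1.47, and Dhcr24, with 0 counts at 26 weeks, at least 14.9-fold lower (adjusted p = 3.04e-07, and adjusted p = 0.0496 with an estimated correlation). Lipid-associated macrophage genes rose in 8 of 16 cases and in 9 adjusted over the list alone, with Apoe, Abca1 and Ctsb at 1.10, 1.31 and 0.63 (adjusted p = 6.01e-05, and adjusted p = 0.0299 with an estimated correlation). Spp1 rose as well (3.60), to 0.643% of its level over all non-SMC-lineage cells. The macrophage-like share of this gate was also larger at 26 weeks. Free RNA of macrophages and doublets with them are thus not excluded for this list or for the leukocyte markers below. Chemokines and NF-kB targets fell in 7 of 13 cases, with Bcl3 and Nfkb1 at -1.83 and -1.38, while 1 rose, Cxcl12 at 2.07 (adjusted p = 0.00146, and adjusted p = 0.272 with an estimated correlation). Dissociation stress genes fell in 16 of 18 cases, Fosb, Junb and Jun by 2.56, 2.33 and 1.45 (adjusted p = 1.55e-12, and adjusted p = 0.0574 with an estimated correlation). Leukocyte markers rose in 6 of 9 cases and in 7 adjusted over the list alone, with Cd52, Tyrobp and Fcer1g at 4.10, 2.35 and 2.08 (adjusted p = 8.68e-04, and adjusted p = 0.323 with an estimated correlation), and Cd74 rose by 2.25 but was not called without replicate 2 at 26 weeks (1.28, adjusted p = 0.187). Calls numbered 4103 of 11007 genes at 8 weeks (2079 higher, 2024 lower; 2769 and 1485 by library totals), 2845 at 16 weeks (1446 and 1399) and 3385 at 26 weeks (1675 and 1710). Cluster 9 held most of the class at 0, 16 and 26 weeks and 47.1% at 8 weeks.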

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

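The interaction of lineage and week was tested by rule for every gene and antibody named between lineages; the tests with cluster 0 left out and with the stricter filter on cells were written before their result was seen, and the other tests of explanations in this part were chosen after the result was seen.

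The lineage difference changed between 0 and 26 weeks for 23 of the 52 genes named between lineages, by the edgeR test of the interaction. Of all 15136 genes, 3558 were higher and 2435 lower by that test at any fold. The share among the named genes is near that of all genes. ZsGreen1 and Cd200 differed more between the lineages at 26 weeks, by 0.99 and 1.05 on the log2 scale. Some named genes that were far lower in the SMC lineage at 0 weeks came closer to the other lineage. Ly6a did so by 7.12, Dcn by 6.85, Tgfbi by 5.09, Cd34 by 4.22, Scara5 by 3.05, Dpep1 by 2.06 and Gsn by 1.19. The complement genes named between lineages did so as well, C1ra by 3.53, C1s1 by 3.46, C2 by 1.56 and Serping1 by 1.00. No gene list was tested for the interaction, so these values speak for the named genes alone. The named genes of the TGF-beta response with a higher level in the SMC lineage gained, Ltbp1 by 1.14, Tgfb2 by 1.07 and Ccn2 by 0.94. Ptprc and Ecscr moved by 3.20 and 1.40, while Lgals3, Vwf and Cdh5 went the other way by -3.11, -1.93 and -4.98. The mitochondrial genes mt-Co3 and mt-Co1 moved by -0.34 and 0.25. Among 12 named antibodies, 5 moved towards the other lineage, CD11b by 3.18, I-A-I-E by 2.75, CD45 by 2.60, CD48 by 2.26 and CD38 by 2.13. Of all 128 antibodies, 27 were higher and 13 lower by the same test at any fold. Acta2 at 26 against 0 weeks stood at 1.91 in endothelial-like and -1.25 in fibroblast-like cells, with every replicate on opposite sides. The difference between these classes was not tested. Acta2 also fell over all cells of the negative gate, so free RNA is not excluded for its fall in fibroblast-like cells.

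Dissociation stress genes were higher in the 0-week captures, and more members fell than rose at 26 weeks in 4 of 4 classes from both lineages, although in endothelial-like cells only 8 of 18 fell and the list did not pass (adjusted p = 0.0956). With cluster 0 of the contractile SMC-like class left out 12 genes fell in place of 13, which argues against that cluster as the whole of it, but 4 rose in place of 1 and the median log2 fold change of the 18 members shrank from -1.23 to -0.40. With at most 10% mitochondrial counts and at least 500 genes per cell 13 genes fell, but this removed 0.906% of the contractile SMC-like cells at 0 weeks and cannot decide on damaged cells. Against 8 weeks, 5 members rose and 5 fell in contractile SMC-like, 7 rose and 4 fell in fibroblast-like and 6 rose and 0 fell in endothelial-like cells, whereas 1 rose and 11 fell in macrophage-like cells, where the change was not confined to the 0-week captures. Handling of the 0-week captures may be the source, but each week was its own capture, so handling and diet cannot be told apart, and a biological fall of these genes on the diet stays open and untested.

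In replicate 1 of the non-SMC lineage at 8 weeks, 663 contractile SMC-like cells (with clusters 1 and 5) made up 27.9% of the matrix and held 19.2 CPM of 4 Y-linked genes, 16.2% of the level in fibroblast-like cells of that matrix. The same cells of 9 other non-SMC matrices held 70.5% to 151%, and replicate 2 at 0 weeks 32.9%. Leaked labelled cells, cells of a female and low depth are argued against, as ZsGreen1 RNA was 1.56% of the lowest SMC-lineage matrix, Xist had 0 transcripts (3 counts would be 0.440 CPM), and at 2000 UMIs per cell 96.4% of these cells had no Y-linked transcript against 81.2% of fibroblast-like cells. Loss of the Y chromosome in smooth muscle cells may account for it, since all 4 genes were low, the highest at 18.6% of its level in fibroblast-like cells; the Myh11-driven Cre used in such mice lies on the Y chromosome, and cells without it would not switch on ZsGreen1. This was found and tested on the same matrix and is a hypothesis.

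Cd200 RNA and the CD200 antibody ordered the classes differently, with less RNA in contractile SMC-like than in endothelial-like cells in 8 of 10 matrices of the negative gate (ratio 0.536 to 1.37, median 0.858) but more antibody on the former in each; in the other 2 both went the same way. Free Cd200 RNA is argued against, since the RNA of endothelial-like cells was at least 24.3 times that of macrophage-like cells in each of the 10 matrices in which the latter had any. The shared total of the panel may account for much of the gap: within these matrices, contractile SMC-like cells exceeded endothelial-like cells 7.58-fold to 22.4-fold per antibody total but 1.21-fold to 2.13-fold per cell. Contractile SMC-like cells also held 0.855 to 2.48 times the RNA molecules, so the panel total, cell size and a difference in protein cannot be told apart. Translation, shedding by the digestion enzymes and antibody access were not tested.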

How the results depend on the processing

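The changes of weeks compared, of cluster 0 and of cluster 17 given here were chosen after the data were seen. Where a value moved, the cause was not tested unless fewer samples make it plain. Among named results other than counts of calls, 1632 stayed on their side of the threshold under the other alternatives, 82 lost and 12 gained a call, 4 reversed and 2 moved; leaving out 1 replicate, 4459 stayed, 30 lost and 10 gained a call. Most lost calls were gene lists with an estimated correlation.

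Per cell, CD200, CD49a and CD49d at 26 weeks reversed to 0.39, 0.083 and 0.18, and CD200 on modulated against contractile cells to 0.43. The same scaling gave 93, 118 and 116 antibodies at 8, 16 and 26 weeks in the SMC lineage and 104 between lineages at 26 weeks. Library totals gave 103 antibodies for modulated against contractile and 102 against fibroblast-like cells. DESeq2 gave 474 endothelial-like genes at 16 weeks. At 26 against 8 weeks, contractile SMC-like cells gave 4172 (2048 higher, 2124 lower) and endothelial-like cells 1207 (676 and 531). With cluster 17, macrophage-like cells gave 3772, 4921 and 6644. At Leiden resolution 0.5, 5 classes passed in either lineage, and fibroblast-like cells of the SMC lineage stood 0.164 points higher at 26 weeks in place of lower.

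Leaving out each replicate, the CD200 antibody ranged from 4.59 to 5.08, 4.30 to 5.11, 4.40 to 4.86 and 4.88 to 5.25 at 0, 8, 16 and 26 weeks, and Cd200 RNA from 0.01 to 0.18, 0.87 to 1.22, 0.77 to 0.88 and 1.05 to 1.23. Genes called between lineages ranged from 5323 to 5553 over the weeks and 5185 to 5695, 4688 to 5641, 5087 to 5386 and 5162 to 5536 within them. At 8, 16 and 26 weeks the SMC lineage gave 4017 to 5201, 5360 to 6566 and 7657 to 8650 genes, contractile SMC-like cells 4073 to 4923, 4250 to 5311 and 5580 to 6561, macrophage-like 662 to 1679, 1396 to 2411 and 2989 to 4381, endothelial-like 259 to 567, 378 to 767 and 1644 to 2424, and fibroblast-like 3236 to 4238, 2055 to 2870 and 2317 to 3480. Antibodies between lineages ranged from 66 to 70, and 55 to 73, 74 to 83, 62 to 78 and 56 to 60 by week; over time 14 to 29, 31 to 48 and 51 to 68; modulated against contractile 54 to 74 and against fibroblast-like 53 to 73. Classes passing ranged from 8 to 10 and 8 to 11.

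Same-numbered matrices of both lineages carry the same leading tag and correlated over 0.1 in 7 of 12 pairs (median 0.163), among them all 3 at 0 weeks, against 2 of 24 pairs with other numbers (median -0.094). The protocols list the tagging before the sort, so equal tags probably mark 1 sample divided over both gates. The labels do not state this. By the rule used, not every pair was over 0.1 nor every sample closest to its own number, so the main tests took no pairing. Such correlations of 3 centred values cannot exclude it. With the number as a replicate block no count moved by over 1.5 times, and the calls were 5468 between lineages, 4862, 6331 and 8449 over time in the SMC lineage, and 68 antibodies between lineages; CD102 at 26 weeks was then not called (adjusted p = 0.0958) and Myh11 in fibroblast-like cells was (0.0300). Without the matrix block, 61 antibodies were called between modulated and contractile cells. The alternatives of the T cell-like comparison were not run.

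Of 100 splits, only 1, the real one, gave as many calls for lineage RNA (5278, highest other 636) and lineage antibodies (68, 18). The same held for modulated against contractile (67, 44) and against fibroblast-like cells (60, 39). The other splits mixed gates or classes that differ by construction, so a lower count was built in. For the lineage and fibroblast-like comparisons they also broke up the captures. These splits thus cannot decide on chance. For each comparison within or against a week the 10 splits are too few for a share under 0.05; the real counts are those of the report, and the highest other was 0, save 3 for RNA between lineages and 1 for SMC-lineage antibodies, both at 16 weeks.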

Other observations

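The genes named in this part were picked after their values were seen, and none of the comparisons described here beyond those of the fixed lists was planned.

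Fixed lists not described so far also moved in SMC-lineage cells between 0 and 26 weeks. Of 10 endothelial activation genes, which include Vcam1 and Icam1, 9 rose (camera adjusted p = 1.29e-04, and adjusted p = 0.443 with an estimated correlation). Of 14 interferon-stimulated genes 8 rose (adjusted p = 0.0207, and adjusted p = 0.469 with an estimated correlation), and of 6 MHC class II genes 5 rose (adjusted p = 0.0334, and adjusted p = 0.544 with an estimated correlation), while leukocyte markers rose as well. Of 12 fibroblast markers 9 rose, or 10 adjusted over the list alone (adjusted p = 0.00146, and adjusted p = 0.469 with an estimated correlation). In endothelial-like cells 6 of 10 contractile genes rose, or 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.0271, and adjusted p = 0.358 with an estimated correlation). In fibroblast-like cells 7 of 12 TGF-beta response genes fell and 3 rose, or 8 fell and 3 rose adjusted over the list alone (adjusted p = 0.0335, and adjusted p = 0.323 with an estimated correlation).

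A few short or repetitive transcripts differed between 0 and 26 weeks, some higher and some lower. The snoRNA host gene Snhg9 stood at 6.12, 3.68, 5.85 and 5.24 on the log2 scale at 26 against 0 weeks in contractile SMC-like, macrophage-like, endothelial-like and fibroblast-like cells, with 4.24, 2.97, 4.99 and 4.12 at 8 weeks. Atp5k and Ndufb1-ps, of mitochondrial ATP synthase and complex I, stood at 2.38 and 2.58 in contractile SMC-like cells and 0.65 and 0.73 in fibroblast-like cells at 26 weeks. Lars2, a mitochondrial leucyl-tRNA synthetase whose transcript shares reads with ribosomal RNA in some libraries, stood at -2.00, -3.26, -3.34 and -2.74, and Gm42418, which overlaps a ribosomal RNA gene, at -1.97, -3.67, -2.87 and -2.34 in the same order. No explanation for these was tested.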
